A study of Mus musculus with 6 samples.

How the data were processed

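Beta cells, the insulin-producing cells of the pancreatic islet, were sorted by flow cytometry from islets of female mice of a mixed 129J-C57BL/6 background, per the labels. The mice were wild type (WT) or lacked the transcription factor FoxO1 in beta cells (IKO), because a Cre recombinase driven by the rat insulin promoter had cut out the floxed Foxo1 gene. Both genotypes were taken at 3 stages, which were 3 months of age and nulliparous, 12 months of age and nulliparous, and 12 months of age after 3 pregnancies. The multiparous WT library carried the label NGT and the multiparous IKO library the label DM. The nulliparous libraries carried neither. What these labels mark goes with genotype between the multiparous libraries and with parity within each genotype. It cannot be told apart from either here. The 6 groups held 1 library each. The labels gave no number of animals per library, no sequencing date and no batch.

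The authors deposited a table of FPKM values (fragments scaled by transcript length and by the number mapped), with 1 column per library. Per the labels' protocols, the RNA came from directional poly-A libraries read as paired ends of 100 bases. Per the submitters' processing notes, TopHat, Cufflinks and Cuffdiff were used with the mouse build mm10, and the notes state no versions. FPKM values depend on gene length models, on how reads shared between copies are divided, and on the total over all genes, so a rise of a few very abundant genes lowers the others. Read counts were not used here, so the depth of each library is unknown.

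The table held 23845 rows with values, and 1 row, which held none here, was not analysed. Symbols at more than 1 locus (260 symbols, 758 rows) were left out, because a value could not be tied to 1 place, which left 23087 genes. In 27 rows the symbol had been turned into a calendar date, and these rows were never named. Positions are those of the deposited table in mm10. Its starts count from 0, since 76.6% of the 11991 genes that share their end with the RefSeq table start 1 base before it there, so 1 was added. An exact 0 was treated as a possible failed estimate. Ins1, Ins2 and Iapp, which are among the most abundant messages of a beta cell, were listed at 0 in all 6 libraries, and 27 further genes were listed at 0 in at least 1 library and at 5 FPKM or more in another. No ratio was formed where either library was listed at 0.

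With 1 library per group, no difference between a pair of libraries could be tested. In each of 7 pairs of libraries (IKO against WT at each stage, 12 against 3 months nulliparous in each genotype, multiparous against nulliparous at 12 months in each genotype), the log2 ratio of FPKM + 1 was taken. Genes were counted where it reached 1 in size, a 2-fold difference on that scale, and where at least 1 of both libraries had 5 FPKM. Adding 1 understates the change of genes with low values. For 25 gene lists, the median log2 ratio of members with a mean FPKM of at least 1 was set against 10000 random lists of the same size matched on mean expression in 20 bins; its percentile describes these libraries and is not a p-value.

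The model that did use a spread was limma 3.58.1 (R 4.3.3) on log2(FPKM + 1) of the 11131 genes with a mean FPKM of at least 1. It had additive terms for genotype and stage and empirical Bayes moderation with a trend. It left 2 residual degrees of freedom, and a genotype effect that differs between stages counts there as error. Contrasts were IKO against WT over the 3 stages, 12 against 3 months nulliparous (age), and multiparous against nulliparous at 12 months (parity), with Benjamini-Hochberg adjustment and a threshold of 0.05. P-values measure only the spread between these libraries, whose animals are not described. Gene lists with at least 3 measured genes were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation beside it. With the estimated correlation, camera also rests on the 2 residual degrees of freedom, or fewer with a library left out. It can then hardly call a list, so a call lost there does not by itself show correlation between genes. The estimated correlation was 0.926 for acinar markers, 0.629 for delta cell markers and 0.334 for respiratory chain genes. If genes are that correlated, p-values at the preset 0.01 are too small for these 3 lists. The estimate lay between -0.125 and 0.109 for the other lists called with all 6 libraries. On simulated data with 100 genes changed 2-fold and 100 changed 4-fold in the genotype contrast over 11131 genes, the fit recovered 95% and 100% of them, with 15 false calls among 210. That simulation drew all libraries with a like spread, which the measured libraries did not have. It changed only genes with a mean above about 5 FPKM, so the recovery does not cover lower genes such as Aldh1a3.

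Named genes followed a rule fixed before the data were examined. It took Foxo1, Gc, Aldh1a3, Gcg, Ins1, Ins2, Mafa, Pdx1, Nkx6-1, Slc2a2, Ucn3, Neurog3, Sst and Ppy whatever their values. It also took the 10 largest differences each way among genes past 2-fold in each pair, the 10 largest each way among genes shared by the 3 stages or called by limma, and up to 4 members of each list. Gene models and small RNAs were left out. Small RNAs called by limma, Mapk8ip3, Mid1 and members of the further lists were named outside this rule. The designs, the lists and the alternatives for pseudocount, filters, scaling, moderation and left-out libraries were fixed at the same time. Chosen after the data had been seen were 2 further pairs (multiparous at 12 months against nulliparous at 3 months in each genotype), a fit without genes listed at 0, gene lists without the 12-month nulliparous WT library, removal of transcript length and GC trends, and 4 further gene lists. Calculations other than limma used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and the rule for pairs, the list percentile, the limma fit and the trend removal were tested on simulated data.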

Results

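RNA of sorted mouse beta cells was measured in 6 libraries, 1 for each combination of genotype (WT or IKO, which lacks FoxO1 in beta cells) and stage (3 months nulliparous, 12 months nulliparous, 12 months multiparous after 3 pregnancies). The comparisons address what loss of FoxO1 does to beta cell transcripts at rest, with age and after repeated pregnancy. The series title also points to Gc, a vitamin D-binding protein restricted to alpha cells among islet cells, in beta cells that lose their identity. All values are FPKM of 1 library, so a difference between 2 libraries has no replicate behind it. FPKM summed to 269418 to 317286 per library, and 11116 to 11182 genes had at least 1 FPKM.

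The 12-month nulliparous WT library stood apart from the other 5. Across genes, its log2 values correlated with those of the others at r = 0.955 to 0.961, against 0.982 to 0.993 among the other 5; genes are not independent replicates. Chga, the granule protein chromogranin A, was at 10936 FPKM there and at 3625 to 4813 elsewhere. The ribosomal protein genes Rpl39 (1359 FPKM, against 166 to 201 in the others) and Rpl13 (347 against 49.3 to 63.1) were higher there. The hormones of other islet cells were also highest there, with Ppy at 990 FPKM (219 to 361 in the others), Sst at 549 (99.7 to 189) and Gcg at 913 (175 to 655). The acinar markers, genes of digestive enzymes, included 9 with a mean of at least 1 FPKM. All 9 had their highest value in this library, led by Ctrb1 at 29.4 FPKM and Cela2a at 13.2. Some of them pass that filter only through this library. The counts and list calls of the fit across stages are therefore also given without this library. Genes for those fits were still chosen by their mean over all 6 libraries, so the acinar list kept its 9 members. The acinar calls there are not free of this filter.

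Foxo1 (chromosome 3, 52268337 to 52350109, mm10) was lower in the IKO library at every stage. It was at 5.67 FPKM in WT and 0.410 in IKO at 3 months, 7.62 and 0.410 at 12 months nulliparous, and 8.93 and 0.656 at 12 months multiparous, which is 13.8-fold, 18.6-fold and 13.6-fold lower. These ratios divide by IKO values under 1 FPKM without the added 1, so their size is uncertain. Foxo1 was the only gene at least 2-fold different in the same direction at all 3 stages, of 7920 genes compared. Independent lists would share 0.000154 genes in that direction. As the deleted gene, Foxo1 was bound by the design to be low in each IKO library, so that number is no further support. With limma over the 3 stages its log2 difference was -2.48 (SE 0.11, lower in 3 of 3 stages) at an adjusted p of 0.0757. limma called 0 of 11131 genes for genotype. The 180 genes at an unadjusted p under 0.05 were a smaller share than the 0.05 that unchanged genes would give. Without the 12-month nulliparous WT library, its IKO partner adds nothing to this contrast, which then rests on the 3-month and multiparous pairs. In that fit the log2 difference was -2.41 for Foxo1 and 1.29 for the pseudogene Atp6v0c-ps2.

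Aldh1a3 (chromosome 7, 66390893 to 66427477), a retinaldehyde dehydrogenase known as a marker of dedifferentiating beta cells, was higher in IKO at each stage. It stood at 0.624 FPKM in WT and 2.18 in IKO at 3 months, and at 0.776 and 3.31 at 12 months nulliparous. At 12 months multiparous it stood at 0.348 and 5.70. The ratios were 3.49, 4.27 and 16.4. They divide by WT values under 1 FPKM without the added 1, so their size is uncertain. Aldh1a3 reached a mean of 1 FPKM only through its IKO values. Its log2 difference over the stages was 1.52 (SE 0.28, limma adjusted p = 0.923 over all genes); it was the 1 gene of 3 measured dedifferentiation genes called when adjusted over the list alone. Gc (chromosome 5, 89417511 to 89457898) was at 34.3 FPKM in WT and 37.4 in IKO at 3 months, 32.9 and 59.7 at 12 months nulliparous, and 17.7 and 40 at 12 months multiparous, a ratio of 1.09, 1.81 and 2.26. Its log2 difference was 0.70 (SE 0.21), with an adjusted p of 0.923 in limma. Msln, encoding mesothelin, and Mid1, a ubiquitin ligase, were at least 1.5-fold lower at all 3 stages, a threshold chosen after their values were seen. Msln was at 22.1 and 13.2, 14.8 and 7.23, and 16.0 and 6.57 FPKM in WT and IKO in the order of stages, and Mid1 at 27.0 and 14.3, 14.9 and 8.72, and 14.8 and 8.53.

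**Figure D1:**
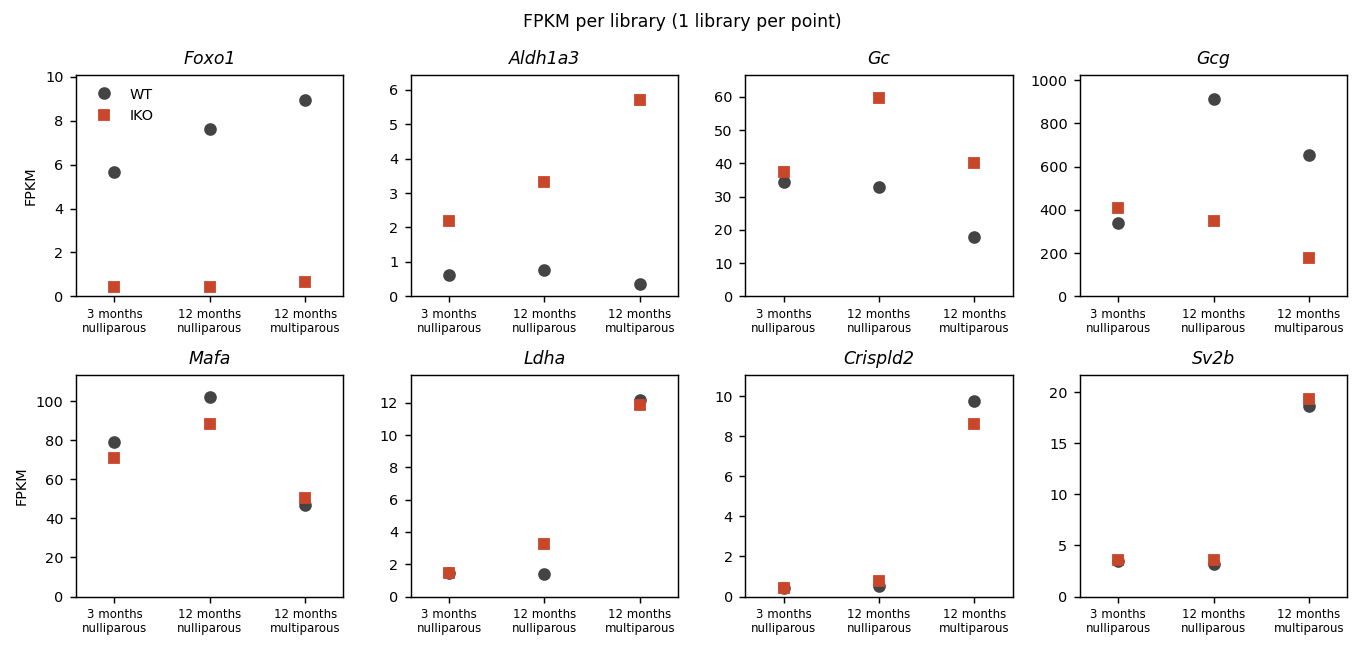
FPKM (vertical axes, linear, from 0) of 8 genes in each library at the 3 stages; grey circles are WT, red squares IKO, and each point is 1 library with no replicate. Foxo1 lies between 5.67 and 8.93 in WT and at or below 0.656 in IKO, Aldh1a3 is highest at 5.70 in multiparous IKO, and Ldha, Crispld2 and Sv2b are highest in both multiparous libraries.

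Between the multiparous libraries, 8 genes were at least 2-fold higher and 10 lower in IKO than in WT, of 8163 compared. Higher besides Aldh1a3 and Gc were Areg, the growth factor amphiregulin, at 7.64 against 3.31 FPKM, AA465934 at 6.40 against 0.942, and Atp6v0c-ps2 at 45.1 against 17.3. Lower besides Foxo1 were Gcg, which encodes glucagon, at 175 against 655 FPKM, Npy, the neuropeptide Y gene, at 8.25 against 22.1, Msln, the histone gene Hist2h2bb at 3.56 against 10.7, the splicing factor gene Cwc22 at 32.3 against 82.8, and Zfp365 at 3.00 against 7.31. Amd1 (5.83 against 0.00636) and Tgoln2 (1.99 against 13.6) also passed the rule, but both have close copies in the genome and jumped between near 0 and several FPKM elsewhere, so their values are uncertain. The somatostatin gene Sst was at 99.7 FPKM in IKO and 172 in WT, and the retinol-binding gene Rbp4, which is in the delta cell list, at 6.01 and 11.0. Over all genes the median absolute log2 ratio was 0.0810.

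At 3 months the IKO and WT libraries were the closest pair, with 4 genes at least 2-fold higher and 5 lower in IKO of 8114 compared and a median absolute log2 ratio of 0.0497. Lower besides Foxo1 were S100a9, a calcium-binding protein gene of myeloid cells, at 1.94 against 6.28 FPKM, and Zfp949, at 6.75 against 14.6. Higher were Cwc22 (30.7 against 14.6) and Atp6v0c-ps2 (5.68 against 1.80). Beta cell identity genes differed little, with Mafa at 70.8 FPKM in IKO and 79.1 in WT, Pdx1 at 66.4 and 65.6, Nkx6-1 at 92.3 and 92.7, and Ucn3 at 182 and 171. The list's median log2 ratio was 0.01 (percentile 31.0 of random lists).

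At 12 months nulliparous, 54 genes were at least 2-fold higher and 270 lower in IKO than in WT, of 8349 compared. This split depended on the scaling, with 142 higher and 156 lower after rescaling without the 20 highest genes. It was 77 and 146 after removal of the length and GC trend. Rescaling each library by its median ratio to the geometric mean of the libraries gave 34 and 344. The lower genes were led by Atp6v0c-ps2, Rpl39, Rps27a, Rpl13, Rpl14 and Foxo1, and the higher ones by Tgoln2, Rpl31-ps12, Dapl1 and S100a11. Apart from Foxo1, each of these genes took its highest or lowest value of the 6 libraries in the WT library that stood apart. Ribosomal protein genes had log2 ratios with an SD of 0.937 in this pair, against 0.171 at 3 months and 0.200 in the multiparous pair. Across genes, the genotype log2 ratios at 3 months and in the multiparous pair correlated at r = 0.382 (0.356 without Foxo1), whereas those of the 12-month nulliparous pair correlated with them at -0.206 and -0.174. Genes are not independent replicates, and the 3 pairs share no library. Trends with transcript length and GC had the same signs at 3 months (rho = -0.193 and 0.185) and in the multiparous pair (-0.180 and 0.355). In the 12-month nulliparous pair both signs were opposite (0.411 and -0.238). The correlations were not recomputed without these trends. A shared trend and a shared genotype difference therefore cannot be told apart in them.

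Of the fixed gene lists, 2 were called for genotype by limma's camera over the 3 stages. The delta cell list was called lower in IKO (median log2 difference -0.67 over 3 measured genes, adjusted p = 0.0213). It rested on Rbp4, lower in 3 of 3 stages, and on Sst, which was level at 3 months (187 FPKM in IKO and 189 in WT), while Sstr3 had a log2 difference of -0.03. The respiratory chain list was called lower (45 of 64 genes below 0, median -0.09, adjusted p = 0.0213), with 0 genes called when adjusted over the list alone. With an estimated correlation the adjusted p was 0.898 for both. Without the 12-month nulliparous WT library, the respiratory chain list turned to higher in IKO (median 0.05, adjusted p = 0.00767), the delta list had an adjusted p of 0.200, and interferon-stimulated genes were higher (median 0.16, adjusted p = 0.00931). With an estimated correlation none of these held, at an adjusted p of 0.869. The 17 FoxO target genes had a median log2 difference of 0.08 over the 3 stages, and their medians per pair were -0.03 at 3 months, 0.13 at 12 months nulliparous and -0.01 in the multiparous pair, with 0 members passing 2-fold in any of these pairs.

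In the multiparous pair, the 3 dedifferentiation genes with a mean of at least 1 FPKM had a median log2 ratio of 0.52 (percentile 100). It was carried by Aldh1a3 and Serpina7, which binds thyroxine (36.3 against 25.1 FPKM). Aldh1a3 passed that filter only through the IKO libraries, and the list's other members were below it or absent. Hes1, the third of the 3 genes, was at 6.05 against 6.15. The 27 beta cell identity genes had a median of 0.09 (percentile 99.6), with Slc2a2, the beta cell glucose transporter, at 51.3 FPKM in IKO and 37.5 in WT, Ucn3 at 125 and 101, Pdx1 at 56.0 and 51.1, Nkx6-1 at 77.6 and 69.8, and Mafa at 50.3 and 46.7. Neurog3, the endocrine progenitor factor, was at 0.461 and 0.339 FPKM. The 9 alpha cell markers had a median of 0.05 (percentile 85.3), with Gc higher and Gcg lower. ER stress genes had a median of 0.11 (percentile 98.7), led by Sdf2l1 at 217 against 163 FPKM.

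Parity was compared within each genotype, and the IKO pair does not use the library that stood apart. The multiparous IKO library carries the label DM, so parity and what DM marks cannot be told apart in that pair. Between the IKO libraries at 12 months, 17 genes were at least 2-fold higher and 23 lower in the multiparous library, of 8209 compared. Higher were Crispld2, a secreted cysteine-rich protein gene (8.60 against 0.784 FPKM), Sv2b, a synaptic vesicle glycoprotein gene (19.3 against 3.61), Gpx3, a secreted glutathione peroxidase (85.2 against 23.5), the nucleotide sugar transporter Slc35d3 (48.7 against 14.5), the lactate dehydrogenase gene Ldha (11.9 against 3.25), and the metallothioneins Mt1 (2849 against 1230) and Mt2 (2450 against 1081). Lower were the stanniocalcin gene Stc2 (1.24 against 12.0), Sfrp5, a Wnt inhibitor (1.45 against 8.72), the protease gene Pappa2 (2.85 against 11.3), Nptx2 (7.27 against 22.5), the gluconeogenic enzyme Fbp1 (5.96 against 16.5) and Ctrb1 (1.72 against 9.89).

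Between the WT libraries at 12 months, 109 genes were higher and 300 lower in the multiparous library, of 8356 compared. The balance turned to 203 higher and 180 lower after rescaling without the 20 highest genes, and it was 129 and 164 after trend removal. Rescaling by the median ratio gave 81 and 377. Crispld2 (9.78 against 0.533 FPKM), Ldha (12.2 against 1.42), Sv2b (18.7 against 3.21) and the decoy receptor gene Tnfrsf11b (11.8 against 2.03) were among the 10 highest ratios. Beside them stood Rpl31-ps12 and Dapl1, which were low in the nulliparous WT library alone, and the lower genes were led by AA465934, Ctrb1, Cela2a and Prss2. limma called 3 genes for parity over both genotypes, all higher. These were Sv2b (log2 difference 2.18, SE 0.10, adjusted p = 0.0430), Crispld2 (2.62, SE 0.14, adjusted p = 0.0454) and the small RNA Snora34, which was listed at 0 in all 4 nulliparous libraries. No gene was called by limma without genes listed at 0 in any library, where 836 had an unadjusted p under 0.05. Sv2b and Crispld2 were listed at 0 in no library, so they stayed in that fit with the same log2 differences. Their calls were lost there all the same. They therefore depended on genes listed at 0, such as Snora34, being tested beside them. Without the nulliparous WT library, limma called 297 genes (155 higher, 142 lower), with Sv2b, Crispld2 and Snora34 among them, from a fit in which the nulliparous side at 12 months was 1 library assumed to vary like the rest.

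**Figure D2:**
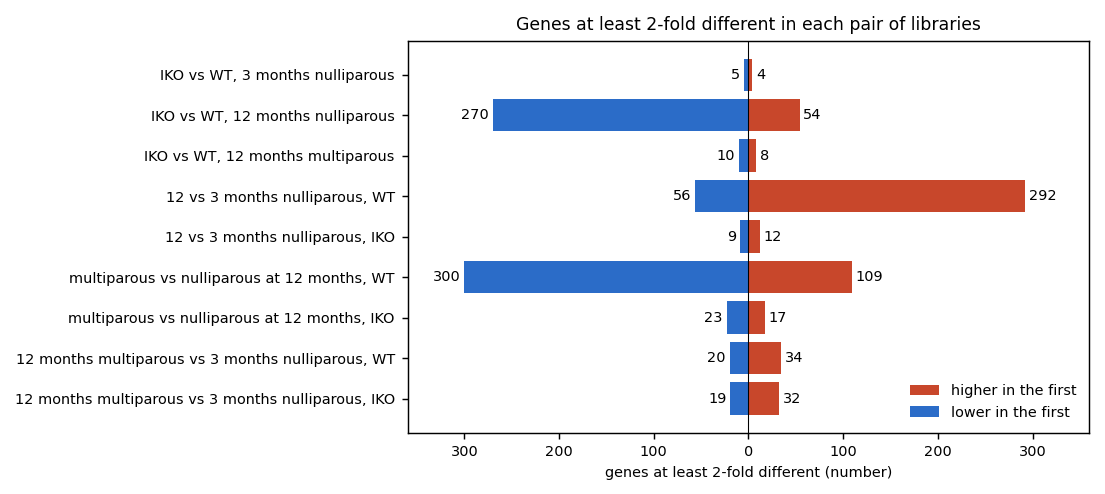
Number of genes at least 2-fold higher (red, to the right) or lower (blue, to the left) in the first library of each pair; the lower 2 pairs were added after the data were seen. The 3 pairs with the 12-month nulliparous WT library reach 324, 348 and 409 genes in total, and the other 6 pairs 9 to 54.

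Glycolysis genes were higher in the multiparous libraries of both genotypes. The list's median log2 ratio was 0.52 between the WT and 0.56 between the IKO libraries (percentile 100 in both), with 13 of 15 members higher in the limma fit and 9 called when adjusted over the list alone, against 0 over all genes. Examples in the order nulliparous and multiparous were Tpi1 at 112 and 195 FPKM in WT and 113 and 185 in IKO, Pgk1 at 61.2 and 88.3 and at 46.6 and 76.5, Pfkl at 30.1 and 47.7 and at 30.0 and 47.3, and Gapdh at 73.6 and 199 and at 128 and 189. Pfkm was lower, at 23.4 and 16.8 and at 22.4 and 19.1. limma's camera gave an adjusted p of 1.37e-07 for the list, and 0.542 with an estimated correlation.

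Beta cell identity genes were lower in the multiparous libraries, with 20 of 27 below 0 in the limma fit (median log2 difference -0.16, camera adjusted p = 0.00122, and 0.542 with an estimated correlation). The list's median log2 ratio was -0.13 between the IKO libraries (percentile 0) and -0.20 between the WT libraries (percentile 20.4, within the range of random lists). Mafa, an activator of insulin transcription, was at 102 and 46.7 FPKM in WT and at 88.5 and 50.3 in IKO, and was the 1 member called when adjusted over the list alone. Slc2a2 was at 59.1 and 37.5 and at 78.8 and 51.3, Nkx6-1 at 106 and 69.8 and at 95.8 and 77.6, and Isl1 went the other way, at 58.9 and 70.1 and at 50.4 and 71.1. Lactogen-responsive genes, which prolactin and placental lactogen induce in islets, were higher (8 of 10; median 0.32, camera adjusted p = 0.00818, and 0.542 with an estimated correlation). Tnfrsf11b, Gbp8 and Wipi1 were called over the list alone, while the prolactin receptor gene Prlr was lower, at 38.9 and 33.4 FPKM in WT and 53.6 and 36.6 in IKO. Alpha cell markers were lower (7 of 9, median -0.36, adjusted p = 0.0319, and 0.542 with an estimated correlation), with Ttr at 147 and 79.3 and at 176 and 97.9, although Gpx3 in the same list was higher. Without the nulliparous WT library the median was -0.43, not smaller in size, at an adjusted p of 0.300.

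Interferon-stimulated genes were higher in the multiparous libraries (14 of 16; median 0.15, camera adjusted p = 0.010, and 0.657 with an estimated correlation). Their median log2 ratio was 0.28 between the IKO libraries (percentile 100) and 0.10 between the WT libraries (percentile 46.6). Respiratory chain genes were lower (median -0.18, adjusted p = 0.00497, and 0.770 with an estimated correlation), but their median ratio was 0.03 between the IKO libraries (percentile 42.6) and -0.31 between the WT libraries. All 9 acinar markers were lower in the multiparous libraries (median -2.0, adjusted p = 5.89e-11, and 0.542 with an estimated correlation). Their median ratio was -2.59 in WT and -1.60 in IKO, so the nulliparous libraries of both genotypes carried more acinar transcript beside the gene groups above. ER stress genes had a median ratio of 0.18 in WT (percentile 99.3) and 0.27 in IKO (percentile 100).

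Without the nulliparous WT library, camera gave an adjusted p for parity of 6.11e-10 for glycolysis (higher), 0.000967 for beta cell identity (lower), 0.000284 for lactogen-responsive genes (higher), 4.20e-06 for interferon-stimulated genes (higher) and 6.05e-07 for acinar markers (lower). The respiratory chain list was no longer called, and it turned from lower to higher, with a median log2 difference of 0.03. Lists called higher in that fit alone were ER stress genes (adjusted p = 0.0195), immediate early genes (adjusted p = 0.00380) and ductal markers (adjusted p = 0.00496). With an estimated correlation the adjusted p was 0.745 for each called list.

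**Figure D3:**
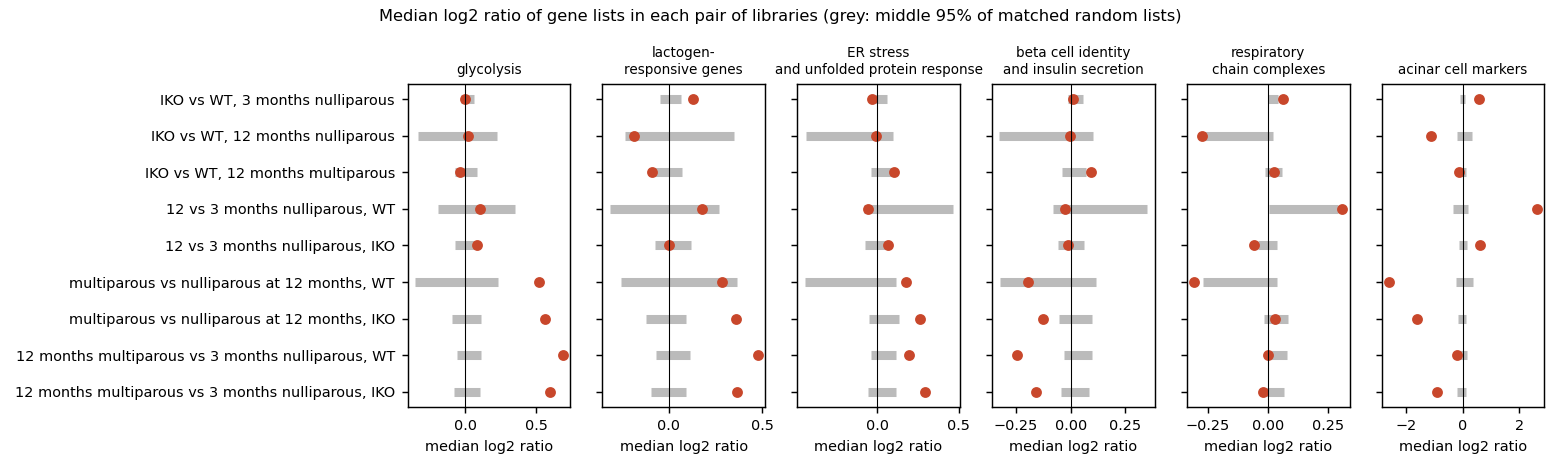
Median log2 ratio (red point, horizontal axes) of 6 gene lists in each pair of libraries, with the middle 95% of medians of matched random lists in grey. Glycolysis genes lie at 0.52 to 0.68 in the 4 pairs with a multiparous first library and a nulliparous second library, and acinar markers reach 2.62 in the WT age pair.

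For age, the IKO pair had 12 genes at least 2-fold higher and 9 lower at 12 than at 3 months nulliparous, of 8209 compared. Higher were Stc2 (12.0 against 2.46 FPKM), Tmem59l (28.7 against 9.89) and Nmnat2, an enzyme of NAD synthesis (11.3 against 3.66). Lower were Rpl29 (41.2 against 131), Rec8, a meiotic cohesin gene (2.84 against 10.4), Cldn11 (5.37 against 14.3), Qpct (2.93 against 7.60) and Npy (14.5 against 31.3). In WT, 292 genes were higher and 56 lower at 12 months, of 8310 compared, led by Atp6v0c-ps2, Ctrb1, Rpl39 and Cela2a. Rescaling without the 20 highest genes gave 152 and 138, trend removal 142 and 96, and rescaling by the median ratio 335 and 50. Values there in the direction of the IKO pair were those of Tmem59l (26.8 against 8.96), Qpct (2.18 against 7.99) and Rec8 (7.47 against 12.7).

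limma called 3 genes for age, Snora2b, Snora3 and Mapk8ip3, each listed at 0 in at least 2 libraries. No gene was called once genes listed at 0 in any library were left out. The 486 genes at an unadjusted p under 0.05 there were a smaller share than the 0.05 that unchanged genes would give. In the fit without the 12-month nulliparous WT library, the IKO library alone stands for 12 months nulliparous and is assumed to vary like the rest. Of the gene lists, camera called acinar markers higher at 12 months (9 of 9, median 1.48, adjusted p = 3.59e-09), immediate early genes higher (median 0.32, adjusted p = 0.00328), respiratory chain genes higher (median 0.15, adjusted p = 0.0307) and interferon-stimulated genes lower (14 of 16, median -0.13, adjusted p = 0.00497). With an estimated correlation the adjusted p was 0.804 for these 4 lists. Between the IKO libraries the medians were 0.62 for acinar markers, 0.14 for immediate early genes, -0.06 for respiratory chain genes and -0.33 for interferon-stimulated genes. Without the 12-month nulliparous WT library, the respiratory chain list was lower at 12 months (adjusted p = 0.00403), the call of immediate early genes was lost (adjusted p = 0.175), FoxO target genes were higher (median 0.14, adjusted p = 0.00268) and ductal markers lower (adjusted p = 0.0283). Acinar markers stayed higher (adjusted p = 0.000239) and interferon-stimulated genes lower (adjusted p = 1.09e-06). With an estimated correlation the adjusted p was 0.797 to 0.799 for the called lists.

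Setting the multiparous libraries at 12 months against the nulliparous ones at 3 months, which was added after the data were seen, uses neither 12-month nulliparous library but joins age and parity. In WT 34 genes were at least 2-fold higher and 20 lower, of 8207 compared, and in IKO 32 and 19, of 8172 compared. Crispld2, Ldha, Sv2b and Gpx3 were among the 10 highest ratios in both genotypes. Among the 10 lowest ratios in both were Cldn11 (0.987 against 8.56 FPKM in WT and 3.32 against 14.3 in IKO), Ugt2b34 (11.2 against 42.1 and 10.2 against 42.0), Nptx2 (8.05 against 29.6 and 7.27 against 26.7) and the cell cycle gene Ccnd1 (11.3 against 29.5 and 13.8 against 34.4). The glycolysis median was 0.68 in WT and 0.59 in IKO, the lactogen-responsive median 0.47 and 0.37, and the ER stress median 0.20 and 0.30 (percentile 100 in each). The beta cell identity median was -0.25 and -0.16 (percentile 0 in both), with Mafa at 46.7 against 79.1 FPKM in WT and 50.3 against 70.8 in IKO, and Ucn3 at 101 against 171 and 125 against 182.

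The remaining lists held no called contrast in the fit of all 6 libraries. In the multiparous genotype pair their medians were -0.00 for MODY genes, -0.16 for ageing and senescence genes, -0.24 for genes normally kept low in beta cells, -0.03 for cell cycle genes, 0.02 for fatty acid oxidation, 0.00 for calcium channels and exocytosis, 0.21 for PP cell markers, 0.05 for ductal, -0.25 for immune and 0.22 for Schwann cell markers. Endothelial and stellate markers had 1 measured gene each, and red blood cell markers had none at a mean FPKM of at least 1.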

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

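The tests of the ribosomal protein genes, of dilution, of the highest genes, of acinar markers, of alpha and delta cell markers, of glycolysis genes and of the splits, and the count of genes kept after each correction, were chosen after the results had been seen; that of the length and GC trend was set before its recount was made.

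Of the named genes, 4 differed at least 2-fold in opposite directions under the same contrast, a difference that was not tested because each group is 1 library. The pseudogene Atp6v0c-ps2 had genotype log2 ratios of 1.26 at 3 months, -5.15 at 12 months nulliparous and 1.33 in the multiparous pair. Its age ratios were 5.38 in WT and -1.03 in IKO, and its parity ratios -2.67 in WT and 3.81 in IKO. Tgoln2 had genotype ratios of 3.86 at 12 months nulliparous and -2.29 in the multiparous pair, age ratios of -3.00 in WT and 1.24 in IKO, and parity ratios of 3.87 in WT and -2.28 in IKO. AA465934 was at -2.10 between the genotypes at 12 months nulliparous and at 1.93 in the multiparous pair. Cwc22 was at 1.02 between the genotypes at 3 months and at -1.33 in the multiparous pair, with 14.6 and 82.8 FPKM in the WT libraries and 30.7 and 32.3 in the IKO libraries.

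The 12-month nulliparous WT library stood apart, with 324 genes at least 2-fold different from its IKO partner against 40 at most in planned pairs without it. A transcript length and GC trend was present (rho = 0.411 with length and -0.238 with GC across genes), but after its removal 223 genes passed against 293 before, 156 of them the same genes in the same direction and 67 new. After rescaling without the 20 highest genes 298 passed against 324 before, 210 of them the same and 88 new, so neither could be the whole cause. Ribosomal protein genes moved apart, with an SD of 0.937 against 0.254 at most in the other planned pairs. In all, 19 genes, 2 of them ribosomal, were at least 2-fold lower there than in each other library. Dilution by RNA of other cell types could not account for these, since it would lower beta cell genes as much, and the 27 beta cell identity genes had a median log2 ratio of 0.0160 to the other libraries (SD 0.345, lowest -0.64). For the ribosomal genes that were higher there, RNA of other cell types stays open, since their proportions in other cells were not measured here. For acinar transcripts, RNA of acinar cells is a candidate source, despite the sort for beta cells. Of the acinar markers with a mean of at least 1 FPKM, 100% peaked there, at up to 29.4 FPKM for Ctrb1. That share is no independent support, since some markers pass the filter only through this library. Cela3b was at 6.84 FPKM there and at 0.144 to 1.31 in the others. A difference of older nulliparous WT mice themselves stays open as untested, since 1 library stands for that group.

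In the multiparous pair Gcg was lower and Gc higher in IKO, although both are alpha cell markers. Fewer alpha cells in the IKO sort could not give the higher Gc, at a log2 ratio of 1.13 where that explanation needs a value below 0. For the lower Gcg and Sst they stay a candidate source, since the other measured alpha and delta markers had a median of 0.0519 (SD 0.380) with members on both sides, and several of them are also expressed by beta cells. A lower expression within cells and a lower share of such cells cannot be told apart here. Genotype stays open as an untested biological explanation, as does whatever the labels NGT and DM mark.

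Glycolysis genes were higher in both multiparous libraries. The nulliparous WT library as the comparison does not account for this, since the median was 0.56 between the IKO libraries. Shared handling of the multiparous libraries, such as time without oxygen during isolation, cannot be told apart from parity, since hypoxia-responsive genes outside glycolysis had a median log2 ratio of 0.61 between the multiparous and 3-month WT libraries and both causes may raise them. No label names a batch, and parity itself stays untested for the same reason.

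For the genotype contrast, 10 splits of the 6 libraries into 3 and 3 exist, too few for a share under 0.05. The real split gave 0 called genes, so 10 of 10 splits, the real one included, reach that number by necessity and the comparison decides nothing. The highest count of another split was 4957, in 2 mirrored splits. Their fit keeps the stage term, so the contrast there rests on the 12-month nulliparous IKO and WT libraries alone, with the spread taken from the other stages.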

How the results depend on the processing

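Fits without genes listed at 0, lists without the 12-month nulliparous WT library, trend removal and the pairs of multiparous against 3-month libraries were chosen after the data were seen. Other alternatives were planned. Depth is unknown, so what it limits could not be measured. Causes were not tested, except where fewer genes or libraries entered.

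For genotype, limma called 0 genes in the fit of all 6 libraries, 1 with a pseudocount of 0.1 and 1 without the stage block, and 2 to 9 with 1 library left out (9 without either 3-month library, 2 without any other). For age it called 3 genes, and 17 to 6039 with 1 library left out (17 without the 3-month WT, 35 the 3-month IKO, 43 the 12-month nulliparous WT, 6039 the 12-month nulliparous IKO, 20 the multiparous WT and 22 the multiparous IKO library). For parity it called 3, and 20 to 6319 (81, 81, 297, 6319, 20 and 28 in the same order). The 6039 and 6319 genes arise where the nulliparous side at 12 months is the WT library alone. For genotype, a library left out also takes its stage partner out of the contrast, so those fits rest on the pairs of the other stages. Parity had 0 calls without a filter (1567 genes at an unadjusted p under 0.05) and 0 at a mean of at least 5 FPKM (508). It also had 0 without genes listed at 0, which left 0 for age as well. With an estimated correlation camera called 0 lists for genotype (2 with the preset one), 0 for age (4) and 0 for parity (7).

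Genes at least 2-fold different moved with a pseudocount of 5 in every pair. Between the genotypes they went from 9 to 3 at 3 months, from 324 to 180 at 12 months nulliparous and from 18 to 11 multiparous; for age from 348 to 190 in WT and from 21 to 6 in IKO; and for parity from 409 to 220 in WT and from 40 to 19 in IKO. Requiring 20 FPKM left 3 and 7 genes between the genotypes at 3 months and multiparous, 6 for age in IKO, and 271 and 17 for parity in WT and IKO. Requiring 1 FPKM gave 34 for age and 70 for parity in IKO. The gene shared by all 3 stages, Foxo1, was lost at a pseudocount of 5 and at 20 FPKM (0 genes). Rescaling without the 20 highest genes shifted the median of the 12-month nulliparous WT library by -0.15 (log2) and changed the split of higher and lower genes there from 54 and 270 to 142 and 156 for genotype, from 292 and 56 to 152 and 138 for age, and from 109 and 300 to 203 and 180 for parity. The respiratory chain list turned direction for genotype, age and parity without the 12-month nulliparous WT library, for parity to a median log2 difference of 0.03. Of the ratios of single genes 746 of the alternative values moved by less than the median absolute ratio of their pair and 274 by more, and of the list medians 408 and 24.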

Other observations

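The 4 gene lists and the tests in this part were chosen after the parity results had been seen. The hypoxia and ATF4 lists were first run in full, and genes whose values had already been seen were then removed from them. The lists are therefore not independent of these libraries. Between IKO and WT at 3 months, the hypoxia, ATF4, guanylate-binding protein and metallothionein lists had percentiles of 0.25, 0, 99.5 and 99.1. An extreme percentile is therefore not particular to parity.

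Guanylate-binding protein genes, which interferon induces, were mostly higher in the multiparous libraries at 12 months (8 of 10 in WT and 9 of 10 in IKO). The 10 measured members had a median log2 ratio of 1.06 between the WT and 0.71 between the IKO libraries at 12 months, and 0.84 and 0.70 against 3 months (percentile 100 in each). Gbp8 is also among the lactogen-responsive genes, and Gbp2 and Gbp3 among the interferon-stimulated genes. The 3 measured metallothionein genes had a median of 1.18 between the IKO libraries and 0.46 between the WT libraries (percentile 95.6). Mt3 went the other way between the IKO libraries, at -0.22, and Mt1 was at 2906 FPKM in multiparous WT, 2849 in multiparous IKO and 1147 to 2115 in the other 4.

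A hypothesis is that the multiparous libraries carry a hypoxia-like response beyond glycolysis. The 18 measured hypoxia-responsive genes had a median log2 ratio of 0.49 between the IKO libraries, 0.61 between the WT libraries, and 0.61 and 0.76 against 3 months in WT and IKO, with a percentile of 100 as the lowest over the pair of IKO libraries and both pairs against 3 months. Between the IKO libraries Mif was at 0.96, Slc16a3, a lactate transporter, at 0.92, and Fam162a at 0.80, while Ndrg1 was at -0.38 and Vegfa at -0.04. The list was also higher at 12 than at 3 months between the nulliparous IKO libraries (median 0.19, 16 of 18 genes above 0, percentile 100), so part of the IKO difference against 3 months was present without parity. This is consistent with such a response, but its source, whether animals or handling, stays open.

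A further hypothesis is that genes of the ATF4 response are lower in the multiparous libraries. The list holds enzymes of amino acid synthesis, amino acid transporters, transfer RNA synthetases and regulators such as Ddit3 and Atf3. Its median over 34 genes was -0.30 between the IKO libraries, with 32 genes below 0, and -0.04 and -0.08 against 3 months in WT and IKO, with a highest percentile of 0.43 over these 3 pairs. Between the WT libraries at 12 months it was 0.12 (percentile 96.8), and the list was higher at 12 than at 3 months between the nulliparous IKO libraries (0.22, 33 genes above 0), so most of the difference between the IKO libraries may come from the nulliparous one. ER stress genes, of which Ddit3, Atf3 and Asns are also in this list, had a higher median in the multiparous IKO library. Between the genotypes the ATF4 list was lower in IKO at 3 months (-0.10, 32 of 34 genes below 0). It was also lower in the multiparous pair (-0.15, 28 below 0), with a percentile of 0 in both. At 12 months nulliparous it was higher in IKO (0.25). The differences against 3 months were thus no larger in size than genotype differences within a stage.

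A segment of chromosome 3 carried along with the floxed Foxo1 allele on a mixed background could also change neighbouring genes. The 36 measured genes within 10 Mb of Foxo1 had a median absolute log2 ratio of 0.0546, averaged over the 3-month and multiparous pairs. Over all genes it was 0.0585 (percentile 34.2 of matched random sets), which gives a broad change of these genes no backing. A median does not show a change of a few of them, so the hypothesis was not settled.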
